A study of Homo sapiens with 8 samples.

How the data were processed

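Gene expression was measured in 8 samples of the human colon cancer lines DLD1 and HCT116, 4 per line, each on 1 Illumina bead array. Per the labels, cells were kept in 1% serum for 36 h and either transduced with shCTRL, shPLD1 or shPLD1/shE2F1 or, with shCTRL, treated with 10 µM PLD1-Inh; the inhibitor is not named further and no vehicle is given. The labels give total RNA made into biotinylated cRNA, name no scanner or software, and number every sample as replicate 1.

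The deposited non-normalised table holds for each array the mean bead signal of 47323 probes as an intensity on a linear scale, with the standard error of the bead signal as an intensity too. It also holds, per the file headers, a detection p-value for each probe and array, which ranks the probe among negative controls. The steps of these p-values are those of 770 controls. The deposited series matrix holds log2 intensity, which from its values the authors had quantile normalised separately within DLD1 and within HCT116, so that levels of the 2 lines in that table do not share a distribution. The arrays differed in the 95th percentile of signal, from 2753 to 3738, or 30.6 to 41.1 times background, and detected between 35.2% and 38.7% of probes, and their number limits the precision.

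All tests started from the non-normalised table. Signal was background corrected with the normexp model in limma 3.58.1 (R 4.3.3), with negative controls inferred from the detection p-values, an offset of 16 was added, values were taken to log2 and all 8 arrays were quantile normalised together. Probes with a detection p under 0.01 on at least 2 arrays were kept, 20084 in all, and the brightest probe stood for each gene, which left 14663 genes. Symbols came from the Entrez identifiers in the file matched to a RefSeq gene table or, where these did not match, from the file, and 92 control probes were left out. Genes of the Y chromosome and the X inactivation transcript are not reported.

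Each line had 1 array per treatment, so that no test within a line and no test of a difference between lines in a response was possible. The treatments were compared by limma (two-sided, empirical Bayes) with cell line and treatment as terms over all 8 arrays, which leaves 3 residual degrees of freedom. The comparisons were PLD1-Inh with shCTRL, shPLD1 with shCTRL, shPLD1/shE2F1 with shPLD1 and shPLD1/shE2F1 with shCTRL, and DLD1 with HCT116 was tested with treatment as a block. Benjamini-Hochberg adjustment was made over all genes of a comparison at 0.05, and again over the 548 tested genes of the lists. As a description of size, genes were counted that were at least 1.5-fold in both lines, beside the number expected if the lines were independent. A named gene whose probe had a detection p of 0.01 or more on every array of 1 group has a fold with a bound: the brighter mean against, per array, the higher of its own level and the lowest level among detected regular probes. An irregular probe also counted as not above background where its level lay under that lowest level, since its detection p need not go with its signal. Where neither group was above background no fold is given. This was added after seeing the data.

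Lists of genes for Wnt, E2F, cell cycle, stress, lipid, interferon, epithelial and other functions were fixed before the data were examined, as were the comparisons, the tests and all settings except where stated. Those with at least 5 measured genes, 27 of 30 lists, were tested with camera (two-sided) at a preset correlation of 0.01 and adjusted over the lists of a comparison, with an estimated correlation and with fry beside it. Medians per line were placed among 10000 random lists of the same size matched on mean expression in 20 bins. The other 3 lists hold markers of fibroblasts, immune cells and endothelium.

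Genes named in the text followed a rule fixed beforehand: PLD1, PLD2, E2F1, CTNNBIP1 and CTNNB1; the 10 largest mean rises and 10 largest falls of each of the 3 main comparisons, or 5 of each direction in the others, among genes past the threshold and, where these were too few, among genes at least 1.5-fold the same way in both lines; and up to 4 members of each list called or 2 of any other. Uncharacterised genes and pseudogenes were skipped. The same ranking among genes with regular probes was added after seeing the data.

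The tables were checked for entries that do not follow their own arithmetic, a check chosen after seeing the data. An entry was marked when its value in the series matrix occurred on no other array of its line and once on its own, when its detection p differed by more than 0.02 from the running median over 101 probes of like signal or was no multiple of a step, when it carried more than 7 significant digits, or when its ranks in both tables differed by more than 300. A probe with 1 value off the set on 1 array and no other sign was not counted, which set aside 21 probes. Tested on 200 entries changed in a copy of the tables, the check found 200 and marked 3 others. Such a change moves a series matrix value away from those of the other arrays, so that finding these entries was built in. It does not show how many real irregular entries the check would find. These steps used Python with pandas and scipy.

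Alternatives were tried for background correction, normalisation between arrays (median scaling), offset (50), the source of the values (series matrix), the filter (none, or detection on all 8 arrays), the probe of a gene (mean of all), the arrays fitted, the variance prior, the block terms, the fold (2-fold), the list test and leaving out each array in turn. Tests without the irregular probes, and tests of lists between DLD1 and HCT116 without each array, were added after seeing the data. Changes were correlated across genes beside 100 simulations of unchanged groups sharing the same arrays. Arrays were simulated with the line means and the spread of the data and 200 genes changed. The inhibitor comparison found 0 of 67 genes changed by a log2 of 1, 18 of 67 changed by 2 and 61 of 66 changed by 4, and 7 others. Camera called the NRF2 target list when raised by a log2 of 1 with an adjusted p of 5.74e-09 and 0 others. The simulated genes varied independently, so that this does not test camera on lists of correlated genes.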

Results

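RNA from DLD1 and HCT116 cells, both established human colon carcinoma lines with constitutive Wnt signalling, was profiled on Illumina bead arrays. Each line was grown in 1% serum for 36 h under 4 conditions: a control hairpin alone (shCTRL), the control hairpin with 10 µM of a phospholipase D1 inhibitor (PLD1-Inh), a hairpin against PLD1 (shPLD1), and hairpins against PLD1 and E2F1 together (shPLD1/shE2F1). PLD1 encodes a phospholipase that makes phosphatidic acid, and E2F1 encodes a transcription factor of cell cycle and apoptosis genes. There was 1 array per line and treatment, 8 in all. There were no replicates within a line, and the errors given are standard errors of a limma fit across both lines with 3 residual degrees of freedom. The number of arrays limits the precision of every value. Between 16670 and 18315 of 47323 probes were detected per array, and 14663 genes were tested. A probe with a detection p of 0.01 or more on every array of a group was not above background there. Nor was an irregular probe, defined below, whose level lay under the lowest level of the detected regular probes of that array, 6.03 to 6.29 in log2. The fold is then given as a bound ("at least"). Means with a standard error are those of the fit and take such levels as measured.

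Arrays of the same line and different treatment correlated across 20084 detected probes at r = 0.944 to 0.991, except those involving HCT116 shPLD1/shE2F1, and arrays of different lines at r = 0.829 to 0.868. The HCT116 shPLD1/shE2F1 array correlated at only 0.791 to 0.851 with the 7 others, including those of its own line. It also had the most detected probes, 18315. CDH1, the adherens junction cadherin, was at a log2 intensity of 11.45 in HCT116 shCTRL, 12.65 with the inhibitor, 11.82 with shPLD1 and 5.19 on this array. KRT19, an epithelial keratin, was at 14.19, 13.87 and 13.83 on the other HCT116 arrays and at 5.59 on this array, and EPCAM, an epithelial adhesion gene, was at 13.90 with shPLD1 and 6.12 here. A further regular EPCAM probe was at 9.44 and 5.34, while an irregular EPCAM probe was at 12.45 with shPLD1 and 13.45 on this array. CDH1, KRT19 and the EPCAM probe at 5.34 were not above background on this array. The intermediate filament gene VIM was at 13.41 on this array and at most at 8.90 on the other HCT116 arrays. The neuronal cadherin gene CDH2 was at 11.42 here and at most at 6.77 on any other array. VIM, CDH2 and ST14, which encodes an epithelial protease, were chosen after their values were seen.

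**Figure D1:**
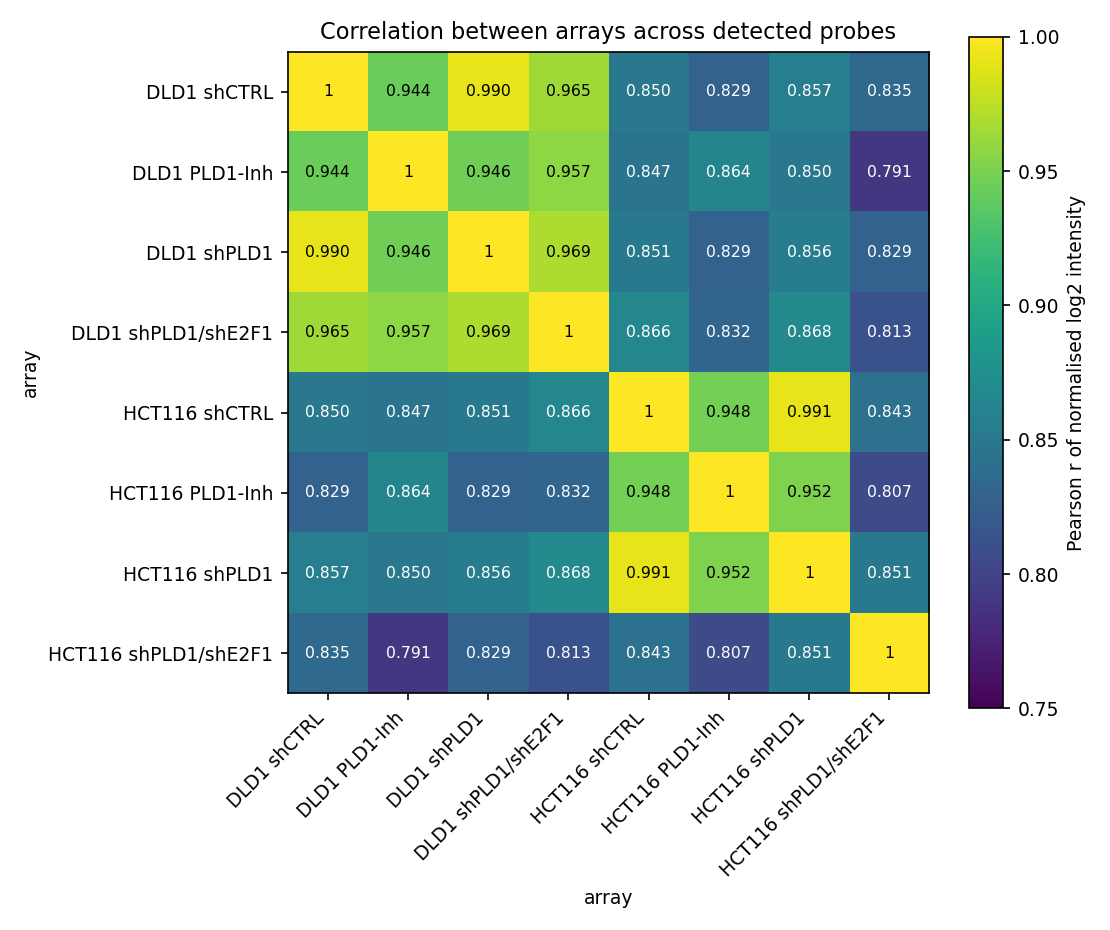
Pearson r of normalised log2 intensity across 20084 detected probes for each pair of the 8 arrays, coloured from 0.75 to 1. The HCT116 shPLD1/shE2F1 array reached 0.851 at most, while the other pairs within a line lay between 0.944 and 0.991.

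**Figure D2:**
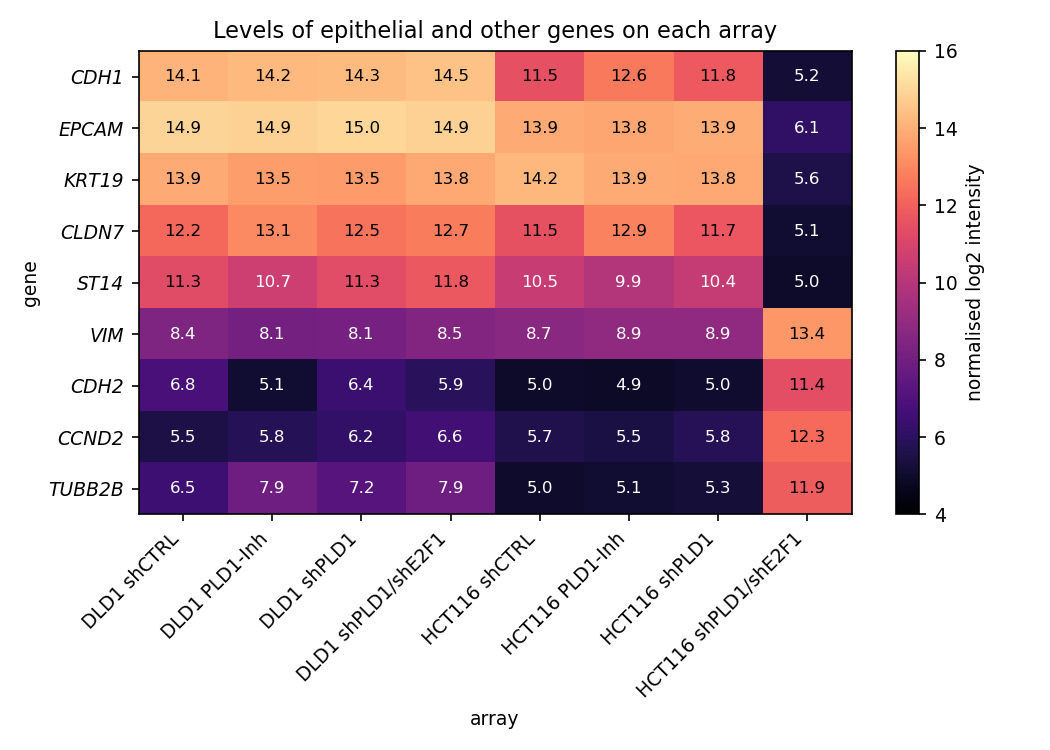
Normalised log2 intensity of 5 epithelial genes (CDH1, EPCAM, KRT19, CLDN7, ST14) and of VIM, CDH2, CCND2 and TUBB2B on each of the 8 arrays, 1 array per column. CDH1 was at 5.19 on the HCT116 shPLD1/shE2F1 array and at 11.45 or more on the other 7.

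Some entries of the deposited tables did not follow the arithmetic of the rest. The deposited normalised table had been quantile normalised within each line, which gives the 4 arrays of a line a common set of values. In 99 probes (0.209% of 47323), which belong to 68 genes, entries lay outside that set, or carried a detection p-value, a number of digits or a rank that did not go with their signal. These probes held 452 such entries: 26, 65, 86 and 64 on the DLD1 arrays with shCTRL, the inhibitor, shPLD1 and shPLD1/shE2F1, and 17, 50, 86 and 58 on the HCT116 arrays in the same order. Of the probes for genes in the lists fixed beforehand, 63 of 1043 (6.04%) were among them, against 36 of 42918 probes (0.0839%) for other genes (Fisher's exact test, two-sided, odds ratio 76.6, p = 3.83e-77). Every probe for PLD1, E2F1, CTNNBIP1 and CTNNB1 was among the 99, called irregular here, and the probe for PLD2 was not. Values were used as deposited, and results resting on irregular probes are named as such.

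The targeted genes came first. PLD1 (chromosome 3) had log2 intensities of 10.71 with shCTRL, 9.96 with the inhibitor, 7.44 with shPLD1 and 8.10 with shPLD1/shE2F1 in DLD1, and of 9.15, 8.04, 6.21 and 6.46 in HCT116, where 6.21 was not above background. E2F1 (chromosome 20) was at 7.87, 7.99, 8.10 and 5.73 in DLD1 and at 7.82, 7.82, 7.93 and 5.31 in HCT116, with 5.73 and 5.31 not above background. CTNNBIP1 (chromosome 1), which encodes an inhibitor of beta-catenin, was at 6.87, 8.63, 8.47 and 6.63 in DLD1 and at 6.84, 10.44, 10.07 and 8.41 in HCT116. CTNNB1 (chromosome 3), the beta-catenin gene, was at 10.10, 8.73, 9.13 and 10.04 in DLD1 and at 11.36, 10.05, 10.58 and 11.91 in HCT116. PLD2 (chromosome 17), the paralog of PLD1 and the regular probe among these, stayed between 6.89 and 7.22 in DLD1 and between 6.90 and 7.67 in HCT116. The levels of PLD1, E2F1, CTNNBIP1 and CTNNB1 all rest on irregular probes, so that the size of both knockdowns could not be checked with a regular probe.

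**Figure D3:**
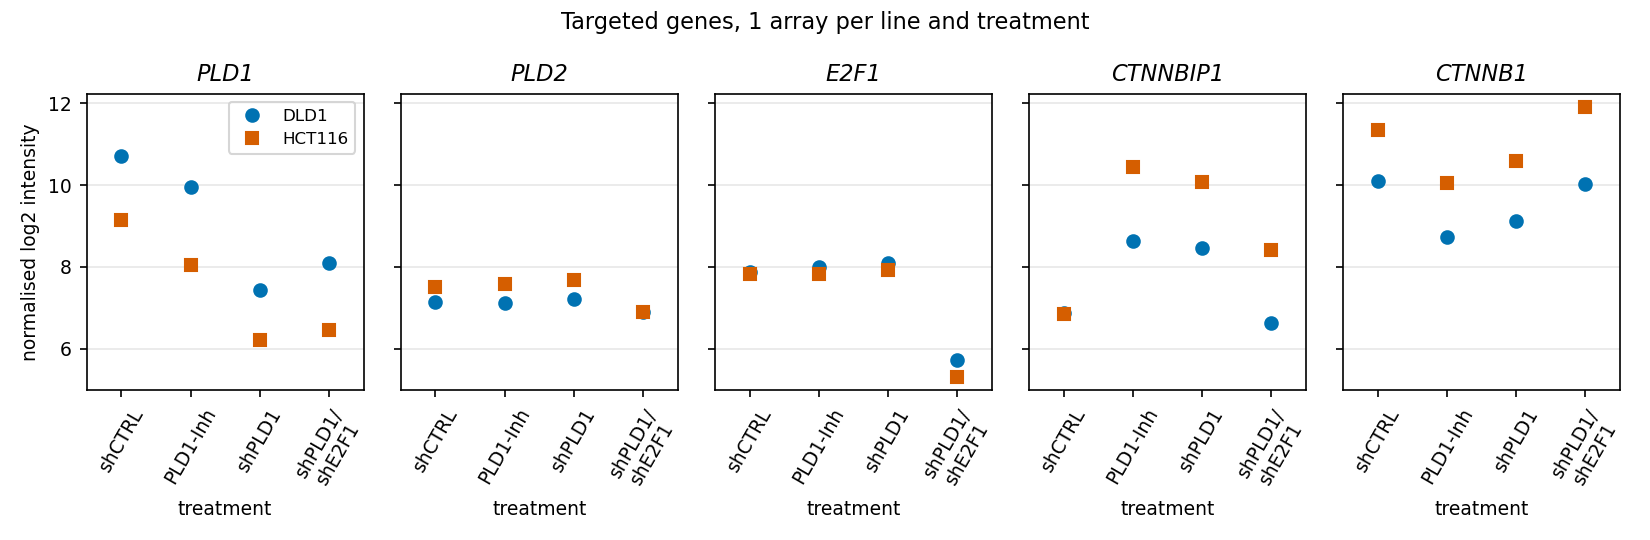
Normalised log2 intensity of the targeted genes PLD1, PLD2, E2F1, CTNNBIP1 and CTNNB1 for the 4 treatments in DLD1 (circles) and HCT116 (squares), 1 array per point. PLD1 was at 7.44 and 6.21 with shPLD1, against 10.71 and 9.15 with shCTRL, and every probe shown except that of PLD2 was irregular.

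The first comparison, PLD1-Inh against shCTRL, asked which genes respond to inhibition of PLD1 activity. Most measured genes of DNA replication and of mitosis were at least 1.5-fold lower in both lines. No single gene passed limma at an adjusted p under 0.05, and no list call of this comparison held with an estimated correlation. CCNE2, the gene of cyclin E2, was 8.02-fold lower in DLD1 and 15.1-fold lower in HCT116 (mean log2 change -3.46 ± 0.65), and MCM4, part of the replicative helicase, was 5.03-fold and 10.3-fold lower (-2.85 ± 0.45). The spread behind these errors takes in the HCT116 shPLD1/shE2F1 array, which this comparison does not use. Without that array the errors of CCNE2 and MCM4 were 0.37 and 0.33. The lack of single genes called thus does not show the absence of a change. Most measured targets of the stress transcription factor ATF4 were at least 1.5-fold higher in both lines. Among them were CHAC1 (2.36-fold in DLD1 and at least 13.5-fold in HCT116) and DDIT4 (4.10-fold and 5.18-fold). Of the measured genes of cholesterol synthesis, most were also at least 1.5-fold higher in both lines, among them the sterol sensor gene INSIG1 (4.35-fold and 6.43-fold).

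Among the targeted genes, the mean log2 change with the inhibitor was -0.93 ± 0.29 for PLD1 (adjusted p = 0.438 by limma), 0.03 ± 0.27 for PLD2 (adjusted p = 0.988), 0.06 ± 0.26 for E2F1 (adjusted p = 0.973), 2.68 ± 0.52 for CTNNBIP1 (adjusted p = 0.280) and -1.34 ± 0.29 for CTNNB1 (adjusted p = 0.336). All except PLD2 rest on irregular probes.

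Of the 44 measured genes of the G1/S and DNA replication list, 40 were at least 1.5-fold lower in both lines and 0 higher. The list fell, with medians of -1.72 in DLD1 and -1.96 in HCT116 (camera, adjusted p = 3.98e-34, and 1.17e-34 without its irregular member; adjusted p = 0.236 with an estimated correlation). Its members included GINS2 (-3.17 ± 0.59), the ribonucleotide reductase gene RRM2 (-2.88 ± 0.35), MCM2 (-2.83 ± 0.57) and CDC45 (-2.85 ± 0.75). The G2/M and mitosis list fell as well, with 34 of 37 genes at least 1.5-fold lower in both lines, 0 higher, and medians of -1.33 and -1.67 (adjusted p = 1.76e-30, and 1.11e-29 without 2 irregular members; adjusted p = 0.236 with an estimated correlation). Examples were the cyclin B1 gene CCNB1 (-2.15 ± 0.33), ANLN (-2.10 ± 0.40) and the proliferation marker MKI67 (-2.05 ± 0.36, at least 2.87-fold in HCT116). The E2F family and pocket protein list fell with 4 of 13 genes at least 1.5-fold lower in both lines, such as E2F8 (-1.76 ± 0.30, at least 3.33-fold and 1.65-fold), and was still called over its 11 members with regular probes (adjusted p = 0.00593, and 0.0221 over the 11; adjusted p = 0.320 with an estimated correlation). Nucleolar genes of the ribosome biogenesis list fell, with 9 of 23 lower in both lines, including UTP20 at -1.48 ± 0.27, at least 1.94-fold and 1.90-fold (adjusted p = 9.85e-08, and 4.80e-07 without its irregular member; adjusted p = 0.320 with an estimated correlation).

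The ATF4 target list rose, with 16 of 21 genes at least 1.5-fold higher in both lines, 0 lower, and medians of 1.06 in DLD1 and 1.81 in HCT116 (adjusted p = 2.09e-14; adjusted p = 0.236 with an estimated correlation). It held 4 irregular members, DDIT3 (3.28 ± 0.72) and NUPR1 (3.26 ± 0.52, at least 15.4-fold and 5.48-fold) among them. Its p without these was 1.53e-10. The ER chaperone list of the unfolded protein response rose, with 8 of 15 genes higher in both lines, among them SEL1L (1.97 ± 0.34, at least 2.84-fold and 4.10-fold) and, from an irregular probe, the BiP gene HSPA5 (2.56 ± 0.67) (adjusted p = 2.68e-09, and 1.44e-07 without 2 irregular members; adjusted p = 0.320 with an estimated correlation). NRF2 targets of the oxidative stress response rose, with 10 of 20 higher and 1 lower in both lines, the aldo-keto reductase gene AKR1C3 at 2.64 ± 0.58 (adjusted p = 9.85e-08, and 4.77e-07 without its irregular member; adjusted p = 0.334 with an estimated correlation). The cholesterol biosynthesis list rose with 15 of 24 genes higher in both lines and 0 lower, medians 0.99 and 0.90 (adjusted p = 1.90e-08; adjusted p = 0.334 with an estimated correlation). Fatty acid synthesis genes rose with 3 of 10 higher in both lines, ACSS2 at 2.40 ± 0.73 and LPIN1 at 1.86 ± 0.35 (adjusted p = 0.000282; adjusted p = 0.334 with an estimated correlation). The NF-kappaB list was called higher with 3 of 16 genes higher in both lines, CCL20 at 2.53 ± 0.67 and at least 2.82-fold in HCT116, although its median was -0.06 in DLD1 and 1.29 in HCT116 (adjusted p = 0.00593; adjusted p = 0.334 with an estimated correlation).

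YAP/TEAD targets fell, with medians of -1.12 in DLD1 and -0.43 in HCT116, CCN1 at -4.71 and -1.01 and ANKRD1 at least 11.9-fold lower in DLD1 and not above background on either HCT116 array (adjusted p = 0.000125, and 0.00353 without 2 irregular members; adjusted p = 0.320 with an estimated correlation). Interferon-stimulated genes fell, with medians of -0.63 and -0.14 and 4 of 29 at least 1.5-fold lower in both lines, USP18 at -1.38 and -0.82 among them (adjusted p = 0.00129; adjusted p = 0.334 with an estimated correlation). Wnt/beta-catenin target genes were called lower (adjusted p = 0.00593; adjusted p = 0.334 with an estimated correlation), with 8 of 31 lower and 1 higher in both lines. The 8 lower genes, with BMP4 (-2.05 ± 0.39), LGR5 (-2.01 ± 0.28, at least 3.03-fold and 2.17-fold), SOX4 (-1.78 ± 0.34) and CD44 (-1.76 ± 0.34) among them, all came from irregular probes, and the 23 members with regular probes showed medians of -0.02 and -0.15 (adjusted p = 0.935). Colon cancer stem cell markers were called lower (adjusted p = 0.00593; adjusted p = 0.320 with an estimated correlation), with medians of 0.18 and -0.04 over the 8 members with regular probes (adjusted p = 0.544).

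Among single genes, the largest increases were those of the small nucleolar RNA genes SNORD3D (4.82 ± 0.74), SNORD3C (3.91 ± 0.56) and SNORD3A (3.33 ± 0.52), of SPRR2D (3.89 ± 0.99, at least 3.43-fold in DLD1) and of INHBE (3.30 ± 0.81, not above background in HCT116 shCTRL). ARHGDIB (-3.28 ± 1.05, at least 23.3-fold in DLD1) and SCARA3 (-3.07 ± 0.91, at least 7.29-fold and 4.59-fold) were among the largest decreases outside the replication genes. None of these passed the test: limma called 0 genes at an adjusted p under 0.05, with a lowest adjusted p of 0.280. There were 1358 genes at an unadjusted p under 0.05 against 733 by chance, and 76 of 548 list genes adjusted over the list alone. In size, 892 genes were at least 1.5-fold higher in both lines (466 by chance) and 1028 lower (498 by chance), with 462 in opposite directions (965 by chance). Under median scaling 1042 were higher and 914 lower, so that the balance of directions turned. The changes of both lines correlated at r = 0.360 across genes. Without either of the shPLD1/shE2F1 arrays the same test called 197 genes, 83 higher and 114 lower, of which 21 had an irregular probe. The lower genes then included 21 of 44 of the replication list and 11 of 37 of the mitosis list, and the higher ones 4 of the ATF4 list. In that fit 190 were called adjusted over the list alone. None of the 14 list calls held with an estimated correlation. The fry test called 3 of them, the replication, mitosis and ATF4 lists, and also called TGF-beta and BMP targets lower (fry, adjusted p = 0.041). In that list ID1, ID2 and ID3 came from irregular probes, with ID2 and ID3 at a mean log2 change of -2.23 each. Fry was not run without irregular probes. Camera did not call that list (adjusted p = 0.471; adjusted p = 0.546 with an estimated correlation), and its medians were 0.37 and 0.15.

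**Figure D4:**
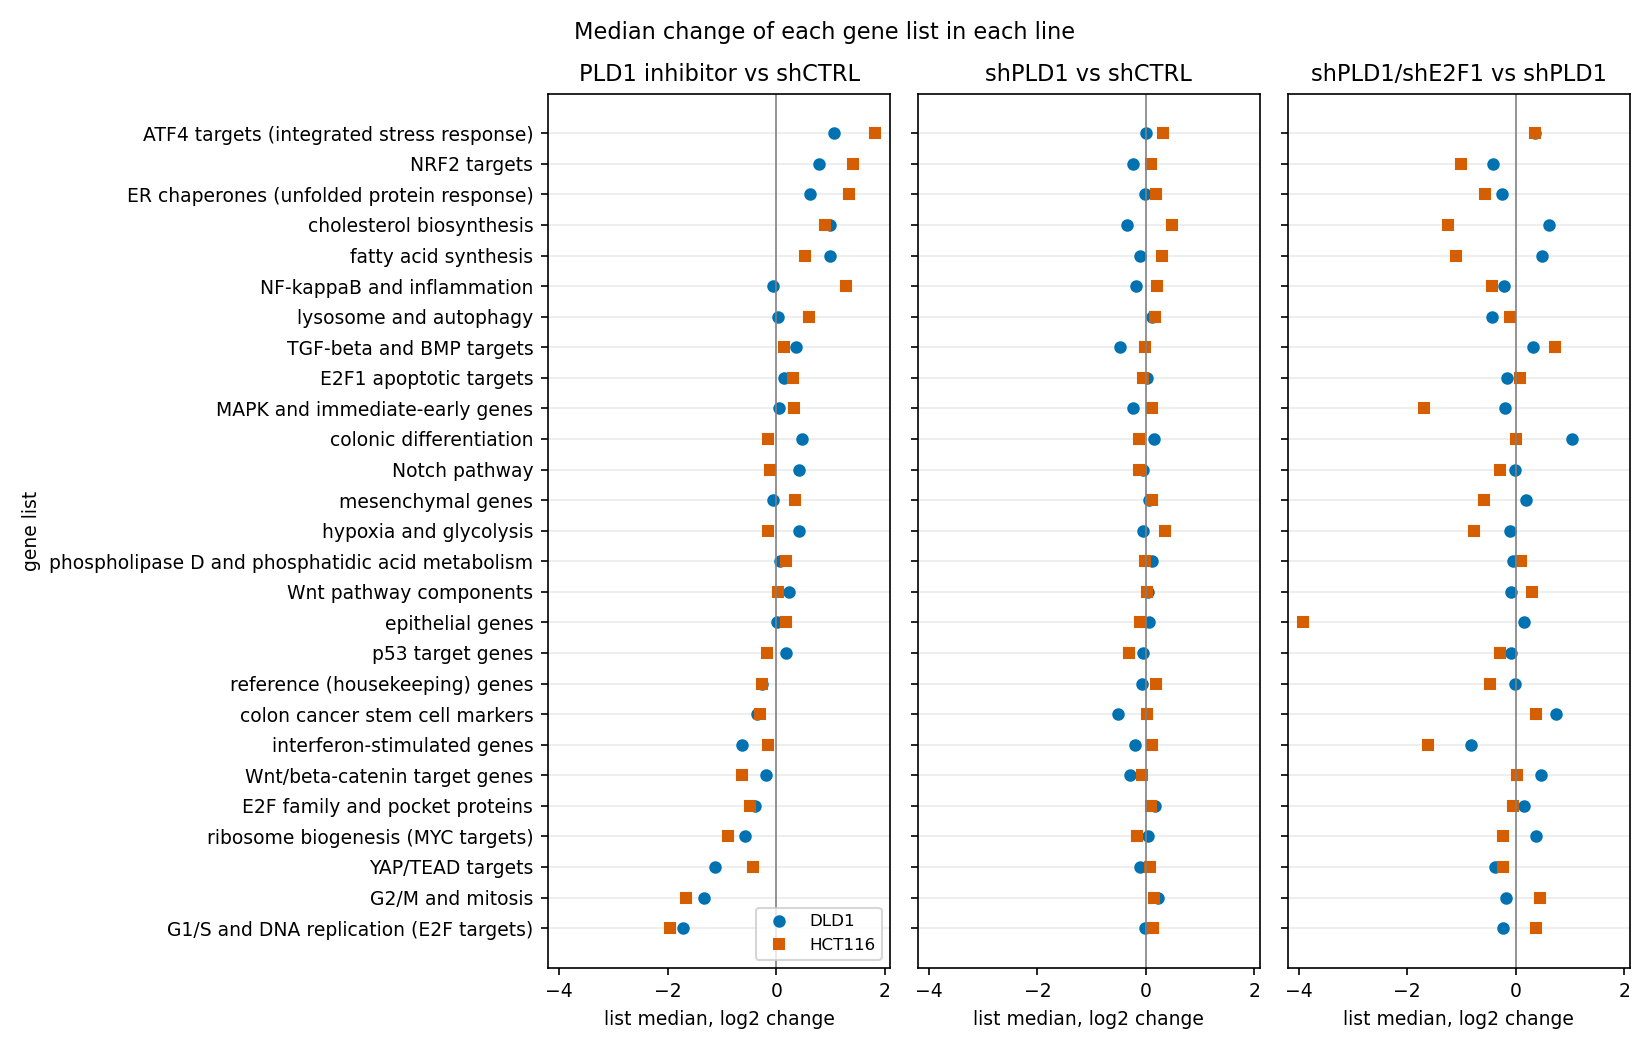
Median log2 change of each of 27 gene lists in DLD1 (circles) and HCT116 (squares) for the 3 main comparisons, lists ordered by their median with the inhibitor. The replication list lay at -1.72 and -1.96 with the inhibitor and at -0.03 and 0.13 with shPLD1, and the epithelial list lay at 0.15 and -3.92 when shE2F1 was added.

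The comparison of shPLD1 with shCTRL asked which genes follow the loss of PLD1 itself. PLD1 was 9.66-fold lower in DLD1 and at least 7.41-fold lower in HCT116 by its irregular probe (mean log2 change -3.11 ± 0.29, adjusted p = 0.905 by limma). Outside the irregular probes the cells differed little: the immediate-early genes FOS, at -1.29 and -1.18, and FOSB, at -0.91 and -0.67, were among the largest decreases. The arrays with shPLD1 and shCTRL correlated at r = 0.990 in DLD1 and at 0.991 in HCT116. The replication genes that were lower with the inhibitor showed medians of -0.03 in DLD1 and 0.13 in HCT116 here (camera, adjusted p = 0.639).

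For the other targeted genes the mean log2 changes were 0.13 ± 0.27 for PLD2, 0.17 ± 0.26 for E2F1, 2.42 ± 0.52 for CTNNBIP1 and -0.87 ± 0.29 for CTNNB1, each with an adjusted p of 1.00. The last 3 rest on irregular probes. The 10 largest increases were all from irregular probes except that of GALR2 (0.80 in DLD1 and at least 0.58 in HCT116): after CTNNBIP1 came the kinase gene PRKAA2 (at least 1.67-fold in HCT116), the nuclear receptor gene NR4A3 (1.91 ± 0.45), and the apoptosis genes BCL2L11 (1.86 ± 0.31, at least 2.36-fold and 3.42-fold), TP73 (1.71 ± 0.28) and PMAIP1 (1.47 ± 0.29). By their detection p PRKAA2, NR4A3 and TP73 were not above background on either DLD1 array, so that they have no fold there, and in HCT116 NR4A3 was at least 2.03-fold and TP73 at least 1.15-fold higher. Of the 10 largest decreases all but that of FOS (-1.24 ± 0.26) were likewise from irregular probes, and after PLD1 they included RB1 (-1.52 ± 0.29), the Wnt transcription factor gene LEF1 (-1.45 ± 1.17, at least 2.12-fold in HCT116), ID2 (-1.39 ± 0.39), LGR5 (-1.35 ± 0.28, at least 2.14-fold in HCT116) and the receptor gene MET (-1.23 ± 0.27). At least 1.5-fold in both lines, 22 genes were higher (14.0 by chance) and 50 lower (10.9 by chance). Of these 13 and 36 had irregular probes. The genes with regular probes gave 9 higher (13.0 by chance) and 14 lower (9.02 by chance).

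The camera test called 9 lists with shPLD1, and only 3 without irregular probes: mitotic genes, hypoxia genes and p53 targets, the last called lower (adjusted p = 0.0330) and not over all its members (adjusted p = 0.0997; adjusted p = 0.463 with an estimated correlation; medians -0.06 and -0.32). Wnt/beta-catenin targets were called lower with 8 of 31 genes lower in both lines, all 8 irregular (adjusted p = 1.85e-08, and 0.906 over the 23 others; adjusted p = 0.264 with an estimated correlation). Colon cancer stem cell markers were called lower with 6 of 14 lower in both lines, CD44 at -1.08 ± 0.34 among them, although the median was 0.01 in HCT116 (adjusted p = 3.05e-09, and 0.622 with the direction turned over the 8 others; adjusted p = 0.171 with an estimated correlation). TGF-beta and BMP targets were called lower through ID2, ID1 (-1.11 ± 0.29) and ID3 (-0.90 ± 0.28), all irregular (adjusted p = 1.52e-05, and 0.508 over the 10 others; adjusted p = 0.200 with an estimated correlation). E2F1 apoptotic targets were called higher through BCL2L11, TP73 and PMAIP1, while the list medians were 0.01 and -0.05 (adjusted p = 0.00106, and 0.392 with the direction turned over the 12 others; adjusted p = 0.411 with an estimated correlation). ATF4 targets were called higher with medians of -0.01 and 0.32 (adjusted p = 0.00124, and 0.225 without 4 irregular members; adjusted p = 0.461 with an estimated correlation).

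Mitotic genes of the G2/M list rose slightly, with medians of 0.23 in DLD1 and 0.15 in HCT116 and the spindle motor gene KIF11 at 0.41 and 0.45, although 0 of 37 were 1.5-fold higher in both lines (adjusted p = 0.00196, and 7.12e-06 without 2 irregular members; adjusted p = 0.705 with an estimated correlation). The hypoxia and glycolysis list, which had no irregular member, was called higher with medians of -0.05 and 0.35, the mitophagy gene BNIP3 at 0.57 ± 0.39 but not above background on either DLD1 array (adjusted p = 0.0146, and 0.0330 without the irregular probes of other lists; adjusted p = 0.705 with an estimated correlation). MAPK and immediate-early genes were called lower, with medians of -0.23 and 0.11 and 5 of 29 lower in both lines (adjusted p = 0.00331, and 0.223 without 2 irregular members; adjusted p = 0.705 with an estimated correlation). Ribosome biogenesis genes were called lower with medians of 0.03 and -0.17 and UTP20 at -0.48 ± 0.27 (adjusted p = 0.0319, and 0.242 without its irregular member DKC1; adjusted p = 0.705 with an estimated correlation).

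By limma, 0 genes were called with shPLD1 at an adjusted p under 0.05. There were 48 at an unadjusted p under 0.05 against 733 by chance, and 1 of 548 list genes adjusted over the list alone. When only the 4 arrays compared were fitted, 7 genes were called and 477 had an unadjusted p under 0.05. The counts of 48 and 477 lay under chance, so that 0 calls do not show the absence of a change. The changes of both lines correlated at r = -0.060 across genes, 56 genes were at least 1.5-fold in opposite directions (24.7 by chance). The fry test called 0 lists. Without HCT116 shCTRL camera called 1 list, and without DLD1 shPLD1 it called 5.

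The comparison of shPLD1/shE2F1 with shPLD1 asked what the E2F1 hairpin adds. There was no group with the E2F1 hairpin alone. Effects of PLD1 loss that need E2F1 thus cannot be told apart from effects of the E2F1 hairpin itself. E2F1 was at least 4.03-fold lower in DLD1 and at least 3.74-fold lower in HCT116 by its irregular probe. Some interferon-stimulated genes were at least 1.5-fold lower in both lines, with ISG15 2.45-fold lower in DLD1 and 12.5-fold lower in HCT116. The call of their list was lost with an estimated correlation. The neuron-specific enolase gene ENO2 was 3.64-fold and 10.6-fold lower, and QPRT, of NAD synthesis, was 7.34-fold and at least 18.5-fold higher. Epithelial genes showed a median log2 change of 0.15 in DLD1 and of -3.92 in HCT116, where they go with the array that stands apart. Every other HCT116 change of this comparison uses that array as well. Of the genes at least 1.5-fold apart in both lines most went opposite ways: 1783 in opposite directions (991 by chance), against 232 higher in both (458 by chance) and 376 lower in both (535 by chance), r = -0.205 across genes. Under median scaling 465 were higher, 342 lower and 2043 opposite, so that the balance of higher and lower turned.

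The targeted genes showed mean log2 changes of -2.49 ± 0.26 for E2F1, 0.45 ± 0.29 for PLD1, -0.55 ± 0.27 for PLD2, -1.75 ± 0.52 for CTNNBIP1 and 1.12 ± 0.29 for CTNNB1, each with an adjusted p of 0.927 by limma. Apart from PLD2 these rest on irregular probes. Among the largest increases in both lines were QPRT (4.03 ± 1.62), the acetate-using enzyme gene ACSS1 (2.75 ± 0.67, at least 3.13-fold and 4.65-fold) and PDE3B (2.33 ± 0.78, at least 3.02-fold in DLD1). The corepressor gene TLE4 was at 0.84 in DLD1 and at least 48.0-fold higher in HCT116. Among the largest decreases were CD163L1 (-4.82 ± 1.48, at least 5.50-fold and 40.2-fold), the protease inhibitor gene CST6 (-4.19 ± 1.42, at least 31.8-fold in HCT116) and VGF (-3.94 ± 1.29). The lactate transporter gene SLC16A3 was at -0.63 in DLD1 and at least 192-fold lower in HCT116, and ANXA1 was at -1.44 and -7.22. All these HCT116 changes use the HCT116 shPLD1/shE2F1 array, which stands apart from its line. The changes spread more widely there across genes (standard deviation 1.32, against 0.58 in DLD1). The ranking by the mean of both lines thus leans on that array, and these sizes need not be effects of the E2F1 hairpin.

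Interferon-stimulated genes fell, with medians of -0.83 in DLD1 and -1.62 in HCT116, 12 of 29 lower in both lines and 0 higher, OASL at -1.11 and -3.75 (camera, adjusted p = 3.04e-10, and 2.41e-05 without the HCT116 shPLD1/shE2F1 array; adjusted p = 0.495 with an estimated correlation). The hypoxia and glycolysis list fell, with medians of -0.10 and -0.77 and ALDOC at -0.84 and -4.45 (adjusted p = 0.000211, and 0.0283 without that array; adjusted p = 0.495 with an estimated correlation). Lysosome and autophagy genes fell, with medians of -0.44 and -0.10 and WIPI1 at -0.44 and -3.33 (adjusted p = 0.0419, 0.00117 without that array, and 0.119 without its irregular member; adjusted p = 0.495 with an estimated correlation). Colonic differentiation genes rose, with a median of 1.03 in DLD1 but -0.00 in HCT116, with the homeobox gene CDX2 at 1.79 and 0.82 (adjusted p = 0.0419, and 0.000768 without that array; adjusted p = 0.495 with an estimated correlation).

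Of the other calls, 4 did not hold over all members without the HCT116 shPLD1/shE2F1 array. Epithelial genes, with KRT19 at 0.32 in DLD1 and at least 223-fold lower in HCT116 and CDH1 at 0.22 and at least 55.3-fold lower, were called lower (adjusted p = 0.000211; adjusted p = 0.598 with an estimated correlation), and without that array turned to higher (adjusted p = 0.334). NRF2 targets were called lower with ABCC2 at least 1.66-fold and 22.5-fold lower (adjusted p = 4.99e-05, 0.000166 without its irregular member, and 0.0991 without that array; adjusted p = 0.499 with an estimated correlation). MAPK and immediate-early genes were called lower with DUSP6 at -0.70 and -6.39 and FOSL1 at -1.27 and -3.96 (adjusted p = 4.81e-05, 1.52e-07 without 2 irregular members, 0.196 without that array, and 0.0438 without both; adjusted p = 0.495 with an estimated correlation). ER chaperones were called lower (adjusted p = 0.0343, 0.133 without 2 irregular members, and 0.196 without that array; adjusted p = 0.630 with an estimated correlation), with DNAJB11 at -0.64 and -0.52. Colon cancer stem cell markers were called higher through 6 irregular members, PROM1 (1.33 ± 0.31, with a detection p of background on HCT116 shPLD1/shE2F1) and ALCAM (1.30 ± 0.28) among them (adjusted p = 0.0180, 0.00142 without that array, and 0.278 with the direction turned over the 8 others; adjusted p = 0.495 with an estimated correlation).

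Without that array the change rests on DLD1 alone, and the DLD1 array is assumed to vary like the others. On that assumption further lists were called. Replication genes, which are E2F targets, were called lower with a median of -0.24 in DLD1 (adjusted p = 0.0283, and 0.0137 without the irregular member), and mitotic genes lower with a median of -0.19 (adjusted p = 0.0283, and 0.00391 without irregular members). With all 8 arrays both were in the other direction and not called (adjusted p = 0.181 and 0.364). Called higher were ribosome biogenesis genes with a median of 0.37 (adjusted p = 1.63e-05), cholesterol synthesis genes with 0.61 (adjusted p = 0.0304) and Wnt/beta-catenin targets with 0.46 (adjusted p = 0.0211, but 0.963 without irregular members). ATF4 targets were called higher only without irregular members (adjusted p = 0.0246, and 0.328 over all). With an estimated correlation the adjusted p was 0.730 for ribosome biogenesis and 0.788 for the 5 others.

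By limma, 0 genes passed when shE2F1 was added, with 460 at an unadjusted p under 0.05 against 733 by chance. Adjusted over the list alone 0 of 548 passed, and fry called 0 lists. The count of 460 again lay under chance, so that 0 calls do not show the absence of a change. Without DLD1 shPLD1/shE2F1, when the change rests on the HCT116 array alone and that array is assumed to vary like the others, 2770 genes were called, and without HCT116 shPLD1/shE2F1 0 were.

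The comparison of shPLD1/shE2F1 with shCTRL gave the joint effect of both hairpins. PLD1 (-2.65 ± 0.29) and E2F1 (-2.32 ± 0.26, at least 3.44-fold and 3.47-fold), each by an irregular probe, had the lowest adjusted p by limma, 0.854. The cyclin D2 gene CCND2 and the tubulin gene TUBB2B were higher, CCND2 at least 1.40-fold in DLD1 and 62.3-fold in HCT116 and TUBB2B 2.69-fold and at least 49.1-fold, which goes with the HCT116 array that stands apart. INHBE, which encodes an activin subunit, was at a log2 change of 1.59 in DLD1 and at least 15.6-fold higher in HCT116, and CD163L1 was at least 6.36-fold and 38.5-fold lower. Some interferon-stimulated genes were at least 1.5-fold lower in both lines, with OASL at -1.64 and -3.43, although the call of their list was lost with an estimated correlation. The largest changes also took in NETO2 (3.43 ± 1.38, at least 26.0-fold in HCT116), ANXA1 (-4.51 ± 1.65), CST6 (-4.05 ± 1.42, at least 49.1-fold in HCT116), CALB2 (-3.77 ± 1.37, at least 1.98-fold and 29.8-fold) and RAB17 (-0.82 in DLD1 and at least 48.0-fold lower in HCT116). All HCT116 changes of this comparison use the array that stands apart, so that their sizes need not be effects of the hairpins.

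Of the 9 lists called, interferon-stimulated genes fell with medians of -0.90 and -1.35 and 14 of 29 lower in both lines (camera, adjusted p = 1.94e-11, and 6.46e-06 without the HCT116 shPLD1/shE2F1 array; adjusted p = 0.630 with an estimated correlation). ATF4 targets rose with medians of 0.28 and 0.58 and the serine synthesis gene PHGDH at 0.91 and 1.72 (adjusted p = 0.00466, 3.62e-05 without 4 irregular members, and 0.0499 without that array; adjusted p = 0.630 with an estimated correlation). Colonic differentiation genes rose with medians of 0.95 and 0.00 (adjusted p = 0.0321, and 0.000822 without that array; adjusted p = 0.630 with an estimated correlation). The other 6 calls were lost over all members without that array. They were, called lower, MAPK genes (adjusted p = 2.54e-07), NRF2 targets (adjusted p = 1.25e-05), epithelial genes (adjusted p = 0.000453), p53 targets (adjusted p = 0.00466, with GDF15 at 0.72 and -7.72) and hypoxia genes (adjusted p = 0.0128), and, called higher, mitotic genes (adjusted p = 0.0177). Their p-values without that array were 0.0606, 0.0606, 0.509, 0.0903, 0.266 and 0.526 in that order, the epithelial and mitotic lists with the direction turned, and MAPK genes were still called over their regular members (adjusted p = 0.0338). Without irregular members the p was 3.45e-08 for MAPK genes, 1.75e-05 for NRF2 targets, 0.0124 for p53 targets and 0.0327 for mitotic genes, and with an estimated correlation the adjusted p was between 0.630 and 0.845.

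Without that array further lists were called, again on DLD1 alone and on the assumption that its array varies like the others. Replication genes, in the other direction with all 8 arrays (adjusted p = 0.148), were then called lower with a median of -0.28 in DLD1 (adjusted p = 0.0413), as were lysosome genes with -0.24 (adjusted p = 0.0196). Called higher were ribosome biogenesis genes with 0.48 (adjusted p = 0.000758), cholesterol synthesis genes with 0.39 (adjusted p = 0.00878) and fatty acid synthesis genes with 0.43 (adjusted p = 0.0228). With an estimated correlation the adjusted p was 0.834 for the lysosome and ribosome lists and 0.899 for the 3 others.

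By limma, 0 genes passed for shPLD1/shE2F1 against shCTRL, with 451 at an unadjusted p under 0.05 against 733 by chance. Adjusted over the list alone 3 of 548 passed, and fry called 0 lists. The count of 451 lay under chance as well, so that 0 calls do not show the absence of a change. In size, 235 genes were higher in both lines (525 by chance), 385 lower (575 by chance) and 2044 in opposite directions (1098 by chance), r = -0.255 across genes. Under median scaling 458 were higher, 335 lower and 2336 opposite, so that here too the balance of higher and lower turned. Without DLD1 shPLD1/shE2F1 2780 genes were called, on the same assumption, and without HCT116 shPLD1/shE2F1 0 were.

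Whether the inhibitor and the PLD1 hairpin changed the same genes was asked by correlating their mean changes across 14663 genes, which are not independent replicates. The correlation was r = 0.211, with a covariance of 0.0285. Unchanged groups that share the shCTRL arrays gave r = 0.499 and a covariance of 0.0464 in 100 simulations. The simulated noise was the residual spread of the fit, which also holds responses that differ between lines and so can exceed array noise. A simulated r of this size follows from sharing arrays, so that the simulations do not show whether the overlap was above or below chance. Between lines, which share no array, r was -0.066 and -0.018. The 65 tested genes with irregular probes gave r = 0.908 and the others 0.164. For the change with shPLD1 and the change when shE2F1 was added, r was -0.135 with a covariance of -0.0192. Simulations of unchanged groups that share the shPLD1 arrays gave a covariance of -0.140. Their noise also takes in the HCT116 shPLD1/shE2F1 array, so that they are no measure of chance either. Between lines r was -0.074 and -0.120, and the genes with irregular probes gave -0.844 against -0.099 for the others.

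Between DLD1 and HCT116, OLR1, a scavenger receptor gene, was at least 270-fold higher in DLD1 (log2 difference of the fit 9.12 ± 0.36, adjusted p = 0.000371), and S100P (8.67 ± 0.34, above background on 1 of 4 HCT116 arrays), TSPAN8 (at least 229-fold), TM4SF1 (at least 271-fold) and the chemokine gene CXCL5 (at least 158-fold) were higher as well. Each of these 4 had an adjusted p of 0.000340. BEX2 (at least 56.1-fold, adjusted p = 0.000648), the Wnt antagonist gene DKK1 (at least 75.6-fold, adjusted p = 0.0180), RTL8A (at least 41.7-fold, adjusted p = 0.000340), STC2 (at least 46.4-fold, adjusted p = 0.000704) and CHST15 (-6.12 ± 0.54, above background on 1 of 4 DLD1 arrays, adjusted p = 0.00257) were higher in HCT116. PLD1 was higher in DLD1 by its irregular probe (1.59 ± 0.21, adjusted p = 0.0089), and was not above background on 1 of 4 HCT116 arrays.

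NF-kappaB and inflammation genes were higher in DLD1, with 7 of 16 passing the test, LTB at least 8.80-fold and ICAM1 at least 3.94-fold, and a list median of 1.44 (camera, adjusted p = 0.000131; adjusted p = 0.621 with an estimated correlation). YAP/TEAD targets were higher with 7 of 15 passing, CCN1 at 3.10 ± 0.69 (adjusted p = 0.00160; adjusted p = 0.621 with an estimated correlation). Mitotic genes were higher with 7 of 37 passing, ECT2 at 1.43 ± 0.22 (adjusted p = 2.02e-06; adjusted p = 0.621 with an estimated correlation). Colonic differentiation genes were higher with 4 of 8 passing, the goblet cell gene TFF3 at least 91.2-fold and TFF1 at least 7.94-fold (adjusted p = 0.00177; adjusted p = 0.611 with an estimated correlation). Targets of p53 were higher in HCT116, with 5 of 25 passing, TP53INP1 at -3.11 ± 0.20 and BTG2 at -2.44 ± 0.26 (adjusted p = 0.00160; adjusted p = 0.611 with an estimated correlation), as were those of ribosome biogenesis, with 3 of 23 passing, FBL at -1.49 ± 0.20 (adjusted p = 0.000275; adjusted p = 0.621 with an estimated correlation). The epithelial, lysosomal and replication lists were called higher in DLD1 with 1 of 14, 2 of 22 and 2 of 44 genes passing (adjusted p = 0.0342, 0.0342 and 0.0470; adjusted p = 0.756, 0.611 and 0.756 with an estimated correlation). The epithelial call was lost without the HCT116 shPLD1/shE2F1 array, with the median going from 1.87 to 0.41 (adjusted p = 0.153), while the other 8 lists were still called. This test was chosen after the values were seen.

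In all, limma with treatment as a block called 2022 of 14663 genes, 1012 higher in DLD1 and 1010 in HCT116, with 4647 at an unadjusted p under 0.05 and 128 of 548 adjusted over the list alone. The arrays of a line are different treatments of it. These p-values thus measure how steady the difference was across treatments, not a spread between replicate cultures of a line. Under median scaling it called 2392, of which 903 were higher in DLD1 and 1489 in HCT116, so that the even balance did not hold. The count was 602 without either shCTRL array, 698 without either inhibitor array, 489 without either shPLD1 array, 5387 without either shPLD1/shE2F1 array, and 897 over genes detected in all 8 arrays.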

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

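The tests of the irregular entries and of the HCT116 shPLD1/shE2F1 array were chosen after their results were seen, and the splits of the arrays were planned.

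Some values moved in opposite directions in DLD1 and HCT116. When shE2F1 was added, the median of the cholesterol biosynthesis list was -1.26 in HCT116, below all of 10000 random lists (percentile 0), and 0.61 in DLD1 (percentile 100). Genes at least 1.5-fold in opposite directions numbered 56 with shPLD1, 1783 when shE2F1 was added and 2044 for shPLD1/shE2F1 against shCTRL. The cholesterol, 1783 and 2044 values for HCT116 all rest on its shPLD1/shE2F1 array, which lay apart from its line, so that they need not be a difference between the lines. With 1 array per line and treatment the difference between lines was not tested.

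The irregular entries concentrated on genes of the lists. Ties and rounding in the authors' normalisation would strike genes of any function alike, while the odds of an irregular probe were 76.6 times as high for genes in the lists as for other genes, which argues against ties and rounding as the whole source. A candidate explanation is that values were changed or entered apart from the export of whole arrays: 55.4% of 92 probes off the value set on at least 2 arrays also carried a sign in the non-normalised table, against 0.0106% of 47231 other probes. On HCT116 shPLD1/shE2F1 an irregular EPCAM probe was at 13.45 where regular EPCAM probes were at 5.34, which was not above background, and 6.12, and what led to such entries was not tested. Whether the transcripts themselves changed cannot be told apart from this, since only 9 genes had an irregular and a regular probe: these differed by a median of 0.728 in their log2 change with shPLD1, against 0.187 for pairs of regular probes in 3562 genes (95th percentile 0.543).

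The HCT116 shPLD1/shE2F1 array lay apart from its line. An exchange with another array of the series is argued against by its highest correlation of 0.851, below the 0.944 that other arrays of a line reached at least, and a weak hybridisation by its 18315 detected probes, the most of any array. The changes of DLD1 and HCT116 with the added hairpin correlated at r = -0.205 across genes. The HCT116 change is taken from this same array, so that this cannot tell whether the hairpin acts alike in both lines. RNA of cells other than HCT116 may explain the array, since 51.5% of 169 genes marking HCT116 lay nearer the DLD1 level there and 462 genes detected on the 7 other arrays were not detected, against at most 168 for another array. Of 115 genes marking DLD1 only 18.3% lay nearer the DLD1 level. Markers detected on this array numbered 2 of 10 for fibroblasts, 4 of 10 for immune cells and 1 of 8 for endothelium. These were no more than the highest counts of other arrays, which says nothing of other cell types. A response of HCT116 alone to the hairpins, which could also lower genes marking HCT116, stays open, untested.

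The 2022 genes that differed between DLD1 and HCT116 were set against other splits of the 8 arrays into 4 and 4 with treatment as a block. Of 32 splits that could be fitted, 1, the real one, gave as many genes, and the highest of the others gave 0. The other splits mix arrays of both lines, so that the difference between lines enters their residual spread. A low count was thus built in, and the splits cannot exclude chance for the 2022.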

How the results depend on the processing

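The tests without irregular probes, and of lists between DLD1 and HCT116 with 1 array left out, were chosen after the data were seen, and the other alternatives were planned. Pairing by replicate was not possible because every sample is numbered replicate 1. In the treatment comparisons cell line served as the block, which pairs the arrays by line. Of counts and correlations 195 values stayed the same, 38 moved and 3 reversed; of list tests 578 stayed, 145 weakened and 11 reversed; of named genes 3997 stayed, 139 passed the threshold only under the alternative and 35 reversed. Under median scaling the median change of all genes was at most 0.0897 in the treatment comparisons and -0.0903 for DLD1 against HCT116. Under the same scaling the balance of higher and lower genes at least 1.5-fold in both lines turned from 892 and 1028 to 1042 and 914 with the inhibitor, from 232 and 376 to 465 and 342 with shE2F1 added, and from 235 and 385 to 458 and 335 for shPLD1/shE2F1 against shCTRL. Between DLD1 and HCT116, 1012 and 1010 genes became 903 and 1489.

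The number of genes at least 1.5-fold in the same direction in both lines, 1920 with the inhibitor, was 1270 without background correction and 645 at 2-fold, which is stricter by construction. With shPLD1 it was 72, against 23 at 2-fold and 23 without irregular probes. For shE2F1 added it was 608, against 332 without background correction, 369 from the series matrix, 355 for genes detected in all 8 arrays and 177 at 2-fold. For shPLD1/shE2F1 against shCTRL it was 620, against 307, 336, 346 and 163 in the same order. Fewer genes are tested by construction in all 8 arrays, and otherwise the cause was not tested.

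With only the 4 arrays compared, shPLD1 gave 7 genes. DLD1 and HCT116 differed in 897 genes detected in all 8 arrays, in place of 2022. Lists called numbered 14, 9, 9 and 9 for the inhibitor, shPLD1, shE2F1 added and shPLD1/shE2F1 against shCTRL. With an estimated correlation they were 0, 0, 0 and 0. That correlation is estimated from 3 residual degrees of freedom, and why the calls were lost was not tested. With fry the lists called numbered 4, 0, 0 and 0. TGF-beta and BMP targets, which camera did not call and which hold irregular members, were among the 4, and the cause was not tested. Without irregular probes shPLD1 gave 3 lists.

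Also without irregular probes, Wnt/beta-catenin targets and stem cell markers with the inhibitor reversed (adjusted p = 0.937 and 0.573), as did stem cell markers and E2F1 apoptotic targets with shPLD1 (adjusted p = 0.623 and 0.392) and stem cell markers with shE2F1 added (adjusted p = 0.278). TEAD4 with shPLD1 turned to 0.26, from another probe of the gene. The construction shows the cause, since the members that carried the calls were left out.

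The correlation of the changes with the inhibitor and shPLD1, 0.211, was -0.066 with the first change from DLD1 and the second from HCT116, -0.018 the other way round, and 0.323 in HCT116 alone. For shPLD1 and shE2F1 added, -0.135, it was 0.0026 in HCT116 alone. Changes of different lines share no array, and beyond that the cause was not tested.

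Leaving out 1 array at a time, the inhibitor gave 0 to 197 genes, shE2F1 added 0 to 2770, shPLD1/shE2F1 against shCTRL 0 to 2780, and DLD1 against HCT116 489 to 5387, while shPLD1 gave 0 throughout and 1 to 11 lists. The 197 came without either shPLD1/shE2F1 array and the 2770 and 2780 without DLD1 shPLD1/shE2F1, which leaves 1 array in that treatment, assumed to vary like the others. The 489 came without either shPLD1 array and the 5387 without either shPLD1/shE2F1 array. The other lists called ranged from 12 to 16 with the inhibitor, 7 to 13 for shE2F1 added, 7 to 10 for shPLD1/shE2F1 against shCTRL and, from 9, 7 to 10 for DLD1 against HCT116. Without HCT116 shPLD1/shE2F1 5 lists were gained both for shE2F1 added and for shPLD1/shE2F1 against shCTRL, replication genes among them with the direction turned.

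Some genes and lists reversed when 1 array was left out, with these lowest and highest values. With the inhibitor, log2 changes ran from -0.063 to 0.12 for PLD2, from -0.041 to 0.16 for E2F1, from -0.49 to 2.76 for IL1A and from -0.70 to 2.78 for BIRC3. With shPLD1 they ran from -0.38 to 2.62 for GALR2, from -0.055 to 0.83 for PLK1, from -0.13 to 0.77 for CENPF, from -0.21 to 0.85 for PPP1R13B, from -0.45 to 0.025 for NOP16 and from -1.13 to 0.32 for PMEPA1. In HCT116 shCTRL IL1A and GALR2 were not above background, nor was PMEPA1 on either HCT116 array or in DLD1 shPLD1, so that these values are not sizes. List p-values with shPLD1 ran from 3.45e-05 to 0.984 for ATF4 targets, from 2.04e-07 to 0.455 for hypoxia genes and from 0.00146 to 0.789 for ribosome biogenesis.

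With shE2F1 added they ran from -5.13 to 0.041 for OAS3, from -5.72 to 0.43 for NQO1, from -7.49 to 0.37 for PHLDA1, from -6.94 to 0.22 for SPRY4, from -8.24 to 0.32 for KRT19, from -6.74 to 0.33 for CDH1, from -6.70 to 0.34 for CLDN7 and from -0.18 to 1.53 for LGALS4. The epithelial list p ran from 2.09e-08 to 0.334. Each of these had its lowest value without DLD1 shPLD1/shE2F1 and its highest without HCT116 shPLD1/shE2F1. OAS3, SPRY4, KRT19, CDH1 and CLDN7 were not above background on HCT116 shPLD1/shE2F1, so that their lowest values are not sizes: in HCT116 they were at least 20.7-fold, 64.9-fold, 223-fold, 55.3-fold and 50.9-fold lower. LGALS4 was not above background on either HCT116 array.

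For shPLD1/shE2F1 against shCTRL they ran from -0.48 to 2.54 for ASPM, from -0.24 to 2.27 for CDC25C, from -0.14 to 1.82 for CENPE, from -7.53 to 0.53 for GDF15, from -3.68 to 0.41 for TP53I3, from -5.06 to 0.12 for OAS3, from -5.52 to 0.63 for NQO1, from -7.51 to 0.35 for PHLDA1, from -6.63 to 0.53 for SPRY4, from -6.41 to 0.028 for KRT8, from -6.47 to 0.56 for CLDN7 and from -0.22 to 1.60 for CA2. TP53I3, OAS3, SPRY4 and CLDN7 were not above background on HCT116 shPLD1/shE2F1, and in HCT116 were at least 14.4-fold, 23.2-fold, 56.6-fold and 45.1-fold lower. The p ran from 0.00263 to 0.526 for mitotic genes and from 4.43e-08 to 0.509 for epithelial genes. Leaving out an array leaves the other line alone in that treatment by construction, so that values which differ in sign between lines reverse. Signal over background, 30.6 to 41.1 at the 95th percentile, limits changes of weakly expressed genes.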

Other observations

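The test of the replication genes was chosen after its result was seen, and the markers of other cell types were fixed before.

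Of the markers of other cell types, 1 to 3 of 10 fibroblast genes, 3 to 4 of 10 immune genes and 1 to 3 of 8 endothelial genes were detected per array. The cholesterol biosynthesis list, which rose with the inhibitor, had a median of -0.35 in DLD1 with shPLD1 (percentile 0 of the random lists) and of 0.48 in HCT116 (percentile 100).

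Replication genes with the inhibitor were lower in both lines, with list medians of -1.72 and -1.96, and with shPLD1 showed medians of -0.03 and 0.13. Lower PLD1 RNA would be expected to lower them with shPLD1 too. In DLD1 the median reached 1.56% of that with the inhibitor, and in HCT116 -6.73%, the other direction. Whether lower PLD1 could explain the replication genes cannot be told apart from an effect of the inhibitor on other targets, because the PLD1 probe was irregular, so that the size of the knockdown is not known. An action on other targets was not tested.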
